A study of Mus musculus with 12 samples.

How the data were processed

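RNA was measured by sequencing in 12 mouse samples in 4 groups of 3. Per the labels, bone marrow pro-B cells lacking Ebf1 were transduced with a vector for Ebf1 or for Ebf1-ER. Ebf1-ER joins EBF1 to an estrogen receptor part, so that the fusion is active while 4-hydroxytamoxifen (4OHT) is present. Cells of either construct were collected with 1 µM 4OHT or 72 h after its withdrawal. Per the labels' protocols, the cells grew on OP9 stromal cells with KIT ligand, FLT3 ligand and interleukin 7 at 10 ng/ml, and CD19-positive cells were sorted 3 days after transduction and again after withdrawal. Libraries were made with a low-input kit and read on a NextSeq for 76 cycles.

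The deposited values are read counts over exons, 1 value per gene and sample, made with HOMER's analyzeRepeats without adjustment to the library total, per the file headers. Reads were aligned with STAR 2.6.0b-1 and counted with HOMER 4.8 against mm10 (GRCm38), per the submitters' processing notes. Those notes also name DESeq2 without a version or a use, and no such values were used here. Neither headers nor notes state a strand setting, so overlapping genes and antisense pairs could not be told apart. The table held 24506 genes, of which 18241 had a count in any sample, and no gene symbol was repeated. Coordinates are those of the deposited table.

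The total count per sample ran from 17267406 to 27877063. The ribosomal gene Rn45s took between 12.4% and 24.9% of each total and stayed in the table. Counts with no molecular identifiers can include PCR copies, so limits based on a floor of 3 counts cover counting error only.

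Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 12913 genes. Libraries were scaled by TMM factors of 0.911 to 1.07. A quasi-likelihood model with 1 coefficient per group was fitted to all 12 samples, with 8 residual degrees of freedom, 4.91 prior degrees of freedom and a common biological coefficient of variation of 0.149. The test was the two-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. Expression values are CPM, read counts scaled by the TMM-adjusted library total, as mean ± SD over 3 samples. The labels do not say whether replicates were separate cultures or animals, so the p-values measure only the spread between these samples.

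The 5 comparisons were the withdrawal effect in Ebf1-ER cells, the withdrawal effect in Ebf1 cells, the difference between these effects (the interaction), and Ebf1-ER against Ebf1 with 4OHT and after withdrawal. The comparisons, tests, alternatives, naming rule and 21 gene lists were chosen before the data were examined. The lists cover the B lineage, the pre-B transition, the MYC network, ribosome biogenesis, G1/S, G2/M, CDK inhibitors with p53 targets, the BCL2 family, glycolysis, cholesterol synthesis, cytokine and homing receptors, T, NK and innate lymphoid cells, myeloid cells, dendritic cells with MHC class II, stem and progenitor cells, stroma, erythroid and mast cells, immediate-early genes, interferon-induced genes, histones and estrogen targets. All 399 genes were in the table. A list was tested with at least 3 members past the filter, which left out the erythroid and mast list with 2 of 13 members. Hbb-bt (log2 fold change -0.11) and Tfrc (0.15) of that list did not pass the test after Ebf1-ER withdrawal.

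Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison. Each list was tested again with a correlation estimated from the data, and with fry. A member counts as having risen or fallen where its edgeR adjusted p over all genes was under 0.05. Counts adjusted over the list alone are given beside these.

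The genes named were set by a rule. Ebf1, Esr1, Pax5, Myc and Cd19 were always named. For Ebf1-ER withdrawal and for the difference, the rule took the called members of each list with the largest changes, up to 4 for the B lineage, MYC network, ribosome biogenesis and T, NK and innate lymphoid lists and up to 2 for each other list. It added genes outside the lists with a mean of at least 5 CPM and no overlap between groups, 5 in each direction for Ebf1-ER withdrawal and 3 in each direction elsewhere. Other genes were picked after their values were seen, and this is said where they appear.

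The labels number replicates 1 to 3 in each group without saying what a number marks. Deviations from the group means over 9329 genes correlated between same-numbered samples of different groups at 0.347 to 0.768 in all 18 pairs, each over the limit of 0.1 set for treating numbers as pairs. Replicates 1 and 2 of different groups correlated about as highly, at 0.364 to 0.661 (median 0.498 against 0.549), 4 of 12 samples matched best with their own number in every other group, and replicate 3 ran against the others at -0.717 to -0.410. In each group the median chi-square per gene between replicates 1 and 2 was 1.01 to 2.08, against 4.69 to 9.59 for either with replicate 3 and 0.455 for sampling noise. Replicates 1 and 2 therefore lay closer to each other than to replicate 3, and replicate 3 was treated as a separate batch in the checks. It holds 1 sample per group and allows no test of its own. The main fit, set in advance, had no replicate block, so the difference between replicates enters its residual spread. The fit with the number as a block was run as an alternative.

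The test was tried on simulated counts with known changes before use. For Ebf1-ER withdrawal over 12722 genes, it recovered 25.4%, 88.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 14 false calls among 155. For the difference over 12695 genes, it recovered 2.99%, 43.3% and 84.8%, with 4 false calls among 91. In each simulation only 67, 67 and 66 genes changed at these folds, far fewer than were called in the data. Replicates were drawn independently, without the closeness of replicates 1 and 2, so these rates need not hold here.

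The alternatives tried were DESeq2 size factors, library totals, other expression filters, the replicate number as a block, DESeq2 1.42.0, limma voom, only the groups compared, an estimated correlation or fry for lists, and leaving out each replicate number or library. Added after the data were seen were a batch term for replicates 1 and 2 against 3, the sum of replicates 1 and 2 as 1 sample with and without that term, and the removal of Rn45s and Mir6236. Summing repeated gene symbols could not be run, since no symbol was repeated. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.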

Results

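RNA was read as exon counts per gene in 12 samples of mouse pro-B cells, in 4 groups of 3. The cells lacked Ebf1, which encodes a transcription factor needed for the B lineage, and carried a vector for Ebf1 or Ebf1-ER. With 4OHT, Ebf1-ER samples 1, 2 and 3 held 17267406, 23963913 and 21209778 counts. After 72 h without 4OHT they held 21916145, 27877063 and 23121026. Ebf1 samples held 19277721, 18867239 and 19962778 counts with 4OHT and 21454543, 20299554 and 20246533 after withdrawal. The design asks what changes when EBF1 activity is lost from cells already committed to the B lineage, with Ebf1 cells as the control for drug removal. Whether both constructs started from the same cells was not tested. Differences between constructs, that between the withdrawal effects included, can therefore not be ascribed to the fusion alone.

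Ebf1 itself was read in every sample. Its mean was 431.8 ± 99.5 CPM in Ebf1-ER cells with 4OHT, 652 ± 183 after withdrawal, 439.4 ± 105 in Ebf1 cells with 4OHT and 454.1 ± 80 after withdrawal (SD, n = 3 each). The counts do not separate vector reads from reads of the knockout allele, so they check that Ebf1 RNA was present and not how active its protein was. Esr1, the estrogen receptor gene, stood at 24.7 ± 0.95 and 38.3 ± 1.07 CPM in Ebf1-ER cells and at 20.2 ± 0.433 and 22.5 ± 1.46 CPM in Ebf1 cells. The labels do not state the species of the receptor part, so it is open whether Esr1 counts include any of the fusion. Ebf1 cells, whose vector is for Ebf1 alone, held 20.2 CPM with 4OHT. If the cells' own Esr1 was alike in both constructs, the fusion made up little of the 24.7 CPM in Ebf1-ER cells.

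Withdrawal of 4OHT from Ebf1-ER cells lowered Igll1, Myc and the lists of ribosome biogenesis and cell cycle genes. It raised the lists of T, NK and innate lymphoid, myeloid, dendritic and MHC class II, and stem and progenitor genes. Igll1, which encodes a surrogate light chain of the pre-B-cell receptor (chromosome 16, 16860671 to 16863985, mm10), fell 21.2-fold, from 1077 ± 59.7 to 50.8 ± 8.08 CPM (log2 fold change -4.41, SE 0.127, edgeR adjusted p = 4.94e-10). Myc, a regulator of cell growth (chromosome 15, 61985341 to 61990361), fell 2.75-fold, from 845.6 ± 165 to 307.3 ± 76.6 CPM (log2 fold change -1.46, SE 0.196, adjusted p = 9.09e-05). Kit, a stem cell factor receptor, rose 5.18-fold, from 43 ± 3.15 to 222.4 ± 20.3 CPM (log2 fold change 2.37, SE 0.0957, adjusted p = 2.64e-09). Lyz2, a lysozyme gene of myeloid cells, rose 27.3-fold, from 7.91 ± 1.01 to 217 ± 45.1 CPM (log2 fold change 4.77, SE 0.283, adjusted p = 7.47e-08). Each of these 4 genes moved the same way in 3 of 3 replicate numbers.

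**Figure D1:**
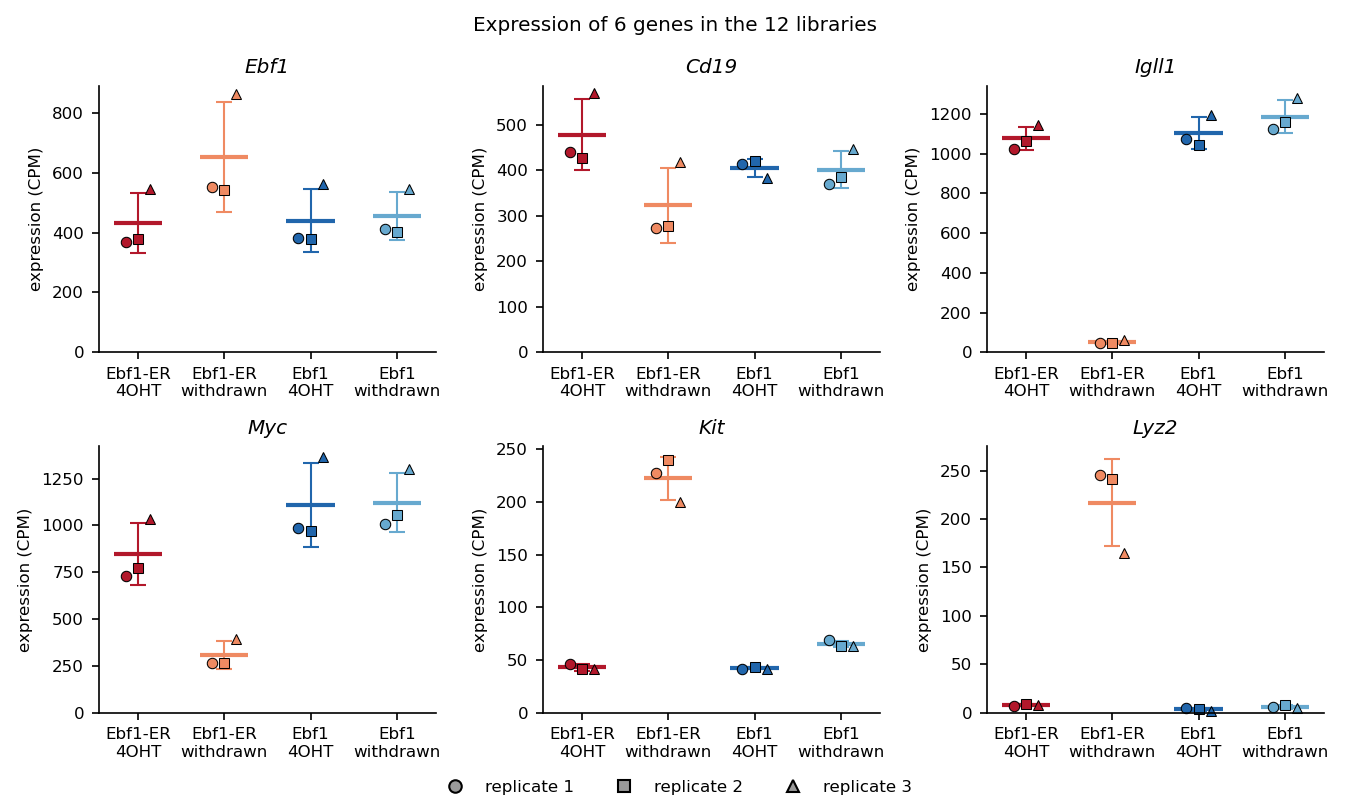
Expression in CPM (linear axes from 0) of 6 genes in the 12 samples, with 1 point per sample shaped by replicate number, a bar at the mean of 3 and whiskers of 1 SD. Igll1 averaged 50.8 CPM in withdrawn Ebf1-ER cells against 1077 with 4OHT, and Myc 307.3 against 845.6, while Kit and Lyz2 were highest in withdrawn Ebf1-ER cells at 222.4 and 217 CPM.

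Of 23 measured B lineage genes, 12 fell, 6 rose and 5 did not pass the test over all genes, and the counts adjusted over the list alone were the same. The list's median log2 fold change was -0.57, and camera called it lower (adjusted p = 0.0048; adjusted p = 0.205 with an estimated correlation). Besides Igll1, the largest falls were in Cplx2 (log2 fold change -2.64, SE 0.13), Bst1 (-2.56, SE 0.226) and Vpreb2 (-2.31, SE 0.172), the last encoding another surrogate light chain. Bst1 fell from 20.2 to 3.41 CPM and stayed above Ebf1 cells, at 1.43 CPM with 4OHT and 0.934 CPM after withdrawal. Blnk and Bank1, adaptor genes of B-cell receptor signalling picked after their values were seen, rose by 1.23 (SE 0.103) and 1.84 (SE 0.17) on the log2 scale. Cd79a, a signalling chain of the receptor also picked after its value was seen, stood at 679.3 CPM with 4OHT and 717.5 CPM after withdrawal (adjusted p = 0.579). Pax5, which maintains B-cell identity, stood at 201.5 ± 30.8 and 222.4 ± 33.9 CPM (adjusted p = 0.513, 0.039 with the replicate number as a block and 0.185 with replicates 1 and 2 summed and a batch term). Cells were sorted for CD19 again after withdrawal, so the levels of Pax5, Cd79a and Cd19 cover only cells that kept CD19. Cd19 fell 1.48-fold (log2 fold change -0.57, SE 0.161, adjusted p = 0.0155), and this call was lost without Ebf1-ER 4OHT replicate 3 (0.0644) and without withdrawn Ebf1-ER replicate 1 (0.0696) or replicate 2 (0.0704), and with replicates 1 and 2 summed (0.143). Ebf1 had a log2 fold change of 0.59 (SE 0.22, adjusted p = 0.0533), which passed with the replicate block (6.78e-08), library totals (0.046), no filter (0.0444), DESeq2 (0.0346) and without Ebf1-ER 4OHT replicate 3 (0.0211) or withdrawn Ebf1-ER replicate 1 (0.0495) or 2 (0.0439).

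Of 20 genes of the pre-B transition, 10 rose and 5 fell (11 and 5 adjusted over the list alone). Cd2, a T- and B-cell surface protein, rose 28.2-fold, and Dntt, the terminal transferase of antigen receptor joining, rose from 38.6 ± 6.27 to 247.6 ± 64.5 CPM. The list's call (adjusted p = 0.04) was lost with an estimated correlation (adjusted p = 0.184), with library totals (0.0609), and without Ebf1-ER 4OHT replicate 1 or 2 or withdrawn Ebf1-ER replicate 3 (0.0611 to 0.075).

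Ribosome biogenesis genes fell together. Of 35, 26 fell and none rose (29 and 0 adjusted over the list alone), with a median log2 fold change of -0.57 (camera adjusted p = 8.51e-11; adjusted p = 0.0342 with an estimated correlation). Polr1b, a subunit of RNA polymerase I, fell by 0.93 (SE 0.09), Rrs1 by 0.88 (SE 0.133), Ppan by 0.87 (SE 0.104) and Srm, the spermidine synthase gene, by 0.84 (SE 0.126) on the log2 scale. In the MYC network of 12 genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.407). Mxd4 and Mxd1, whose products oppose MYC, rose by 1.62 (SE 0.218) and 0.95 (SE 0.183), and Mycl rose by 1.97 (SE 0.517) from 0.16 ± 0.0651 CPM, a call lost with replicates 1 and 2 summed (adjusted p = 0.0742).

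Genes of the cell cycle fell as well. At G1/S, 19 of 27 fell and none rose (20 and 0 adjusted over the list alone; median -0.37, adjusted p = 1.71e-08). Ccnd2, which encodes cyclin D2, fell from 286 ± 48.8 to 136.2 ± 26.5 CPM, and Uhrf1 fell by 0.92 (SE 0.176) on the log2 scale. At G2/M, 12 of 22 fell and none rose (13 and 0 adjusted over the list alone; median -0.31, adjusted p = 8.03e-05), with Aurkb falling by 0.56 (SE 0.103) and Birc5 by 0.50 (SE 0.121), a call lost with replicates 1 and 2 summed (adjusted p = 0.0825). Of 17 histone genes, 7 fell and none rose (8 and 1 adjusted over the list alone; adjusted p = 0.000338; adjusted p = 0.124 with an estimated correlation), Hist1h2ac and Hist1h1b each by 0.72. The call of Hist1h2ac was lost with replicates 1 and 2 summed (adjusted p = 0.0666). Among 18 CDK inhibitor and p53 genes, 8 rose and 4 fell (8 and 5 adjusted over the list alone), the median was 0.02 and the mean 0.00 (-0.00467), and the list was not called (adjusted p = 0.543). Sesn1 rose by 0.99 (SE 0.105) and Cdkn2a fell by 1.46 (SE 0.303). Of 12 BCL2 family genes, 4 rose and 2 fell, also when adjusted over the list alone, and the list was not called (adjusted p = 0.232). Bmf, which promotes cell death, rose 7.87-fold from 10.3 ± 0.157 to 80.8 ± 7.06 CPM, and Bcl2l11 rose by 0.88 (SE 0.142).

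Of 18 glycolysis genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone), with Pfkp falling by 0.92 (SE 0.104) and Hk1 rising by 1.42 (SE 0.154). That list's call (adjusted p = 0.04) was lost with an estimated correlation (adjusted p = 0.277), with library totals (0.0511), with a filter of 1 CPM (0.0745), with replicates 1 and 2 summed (0.0501), and without Ebf1-ER 4OHT replicate 1 or 2 or withdrawn Ebf1-ER replicate 3 (0.0641 to 0.0967). Of 22 cholesterol synthesis genes, 2 fell and 1 rose, also when adjusted over the list alone, and the list was not called (adjusted p = 0.155). Lss, the lanosterol synthase gene, fell by 0.64 (SE 0.0883).

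The lists named for other lineages, for MHC class II and for stem and progenitor cells rose, though their genes need not be absent from B-lineage cells. Of 11 measured T, NK and innate lymphoid genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone; median 1.30, adjusted p = 0.000107). The natural killer receptor gene Klrd1 rose from 3.18 ± 0.17 to 58.2 ± 9.07 CPM, Il18r1 rose 13.2-fold from 1.206 to 16.01 CPM and Nkg7 10.1-fold from 1.452 to 14.69 CPM. Ebf1 cells already held Il18r1 at 7.976 and Nkg7 at 10.81 CPM with 4OHT, and at 10.54 and 19.46 CPM after withdrawal. Klrb1c rested on 2 counts with 4OHT (ratio 30.1, 95% counting interval 8.02 to 254). The other 15 genes of that list, Cd3e among them, stayed below the expression filter. Of 6 measured myeloid genes, 4 rose and none fell, also when adjusted over the list alone (median 3.88, adjusted p = 0.00022), with Fcgr3 rising 22-fold. The other 13 of the 19 myeloid genes, S100a8, Mpo and Csf1r among them, stayed below the expression filter, so the median covers only genes that passed it. Of 12 measured dendritic and MHC class II genes, 11 rose and 1 fell, also when adjusted over the list alone (median 2.91, adjusted p = 2.11e-07). Zbtb46, Batf3 and Cd209a of that list stayed below the expression filter. The MHC class II genes H2-Ab1 and H2-Eb1 rose from 0.236 ± 0.183 to 33.6 ± 2.44 CPM and from 0.551 ± 0.258 to 51.2 ± 8.42 CPM. Of 8 measured stem and progenitor genes, 5 rose and none fell (6 and 0 adjusted over the list alone; adjusted p = 0.000145), Ly6a by 2.75 (SE 0.166) besides Kit. The rest of the 16 genes of that list, Cd34, Meis1 and Gata2 among them, stayed below the expression filter.

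Receptor, response and stromal genes rose too. Of 21 cytokine and homing receptor genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 1.03e-05). Sell, which encodes L-selectin, rose 7.89-fold and S1pr1, an egress receptor gene, 7.25-fold. The gene that fell was Il7r, the interleukin 7 receptor gene, named after its value was seen (log2 fold change -0.83, SE 0.154). Of 17 stromal genes, 12 rose and none fell, also when adjusted over the list alone (median 1.39, adjusted p = 5.01e-06), with Col5a1 reaching 3.38 ± 0.667 CPM and Col1a1 28 ± 12.5 CPM. Lum, Dcn and Postn of that list stayed below the expression filter, Lum and Dcn with 0 counts over all samples. The cultures held OP9 stromal cells, and the measured stromal genes rose beside the receptor and lineage genes. Of 14 immediate-early genes, 8 rose and none fell, also when adjusted over the list alone (adjusted p = 0.000107; adjusted p = 0.0583 with an estimated correlation), among them Ier3 by 4.33 (SE 0.532) and Fos by 2.18 (SE 0.229). Of 11 measured interferon-induced genes, 8 rose and none fell, also when adjusted over the list alone (adjusted p = 0.000455), with Oasl2 rising 14.5-fold and Oas2 13.1-fold. The rest of the 15 genes of that list, Isg15, Mx1, Ifi44 and Cxcl10, stayed below the expression filter. Of 8 estrogen targets, 5 rose and 1 fell, also when adjusted over the list alone (adjusted p = 0.00586), Igfbp4 by 1.06 (SE 0.105) and Pgr, the progesterone receptor gene, from 0.0699 ± 0.079 to 1.91 ± 0.288 CPM. In Ebf1 cells Pgr stood at 79.56 ± 4.13 CPM with 4OHT and 54.57 ± 2.12 CPM after withdrawal, so it stayed far lower in Ebf1-ER cells (log2 difference -4.85 after withdrawal). Esr1 rose 1.55-fold (log2 fold change 0.64, SE 0.0909, adjusted p = 0.000151).

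**Figure D2:**
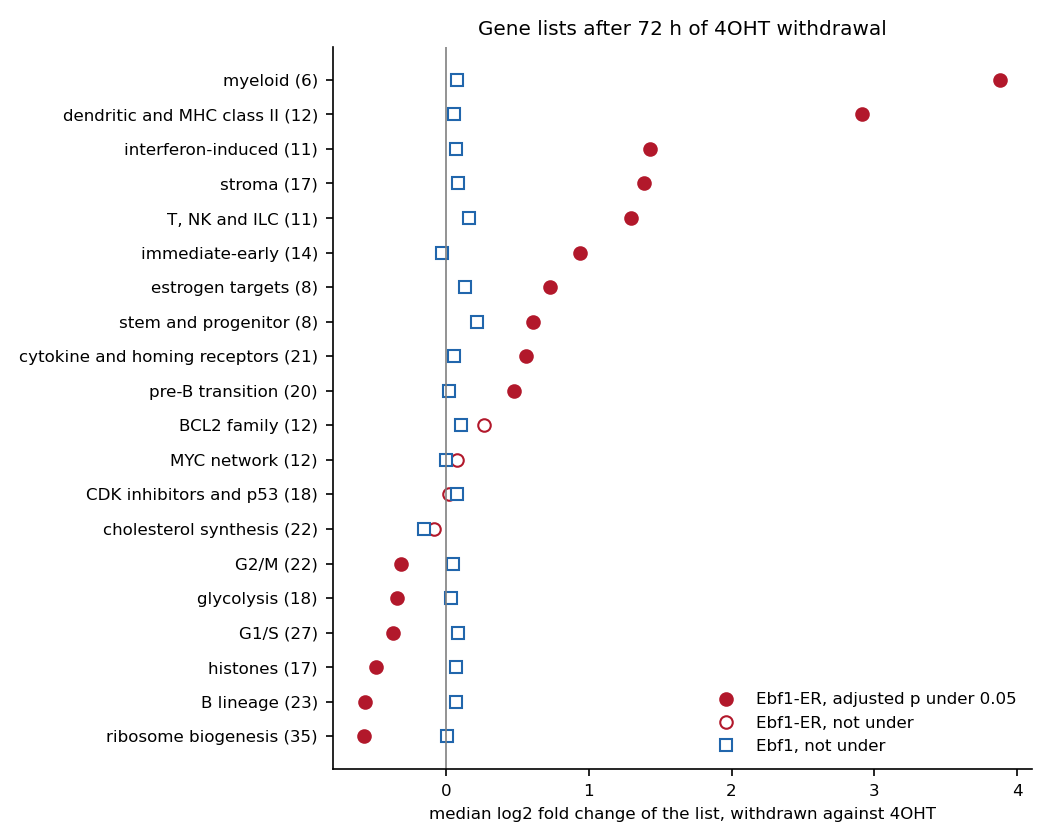
Median log2 fold change (withdrawn against 4OHT) of 20 gene lists in Ebf1-ER cells (red circles) and Ebf1 cells (blue squares), with the number of measured genes in brackets and filled symbols for camera adjusted p under 0.05. In Ebf1-ER cells 16 lists are filled, from -0.57 for ribosome biogenesis to 3.88 for myeloid genes, and in Ebf1 cells 0 are.

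Outside the lists, the largest rises that met the naming rule were in Calm4, a calmodulin-like gene (log2 fold change 8.52, SE 0.71, with 4 counts in the 4OHT group), AA467197 (6.82, SE 0.211), Crisp1 (6.67, SE 0.417), Scn3a, a sodium channel gene (6.63, SE 0.364), and Mir147 (6.32, SE 0.414). Mir147 lies within AA467197 on chromosome 2, so their counts cannot be separated. The largest falls were in Clgn, a chaperone gene (log2 fold change -5.99, SE 0.23), H19, a noncoding RNA (-3.97, SE 0.23), Rragd, a nutrient-sensing GTPase gene (-3.71, SE 0.131), Cd248 (-3.70, SE 0.199) and Gfra1 (-3.16, SE 0.119). Clgn went from 63.1 ± 1.54 to 0.966 ± 0.35 CPM. Across the 12913 genes tested, 4337 changed after Ebf1-ER withdrawal, 2519 higher and 1818 lower (2125 and 2133 with library totals), and 1382 of them by at least 2-fold. Of 20 lists tested, 16 were called, of which 11 were called with an estimated correlation. Replicates 1 and 2 alone gave 7008 genes, and of those with a value in replicate 3, 92.4% had the same sign there, while 6632 genes changed with a batch term 1910 with replicates 1 and 2 summed and 5017 with that sum and a batch term.

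In Ebf1 cells, whose EBF1 does not need the drug, withdrawal of 4OHT changed 47 genes, against 4337 in Ebf1-ER cells. With the replicate number as a block it changed 535 against 6437. Myc and the 4 other genes always named were not called in Ebf1 cells in either fit. Cybb, the NADPH oxidase gene of phagocytes, rose 3.77-fold from 4.05 ± 1.12 to 15.3 ± 0.812 CPM (log2 fold change 1.91, SE 0.167, edgeR adjusted p = 0.00049). Cdh17, a cadherin gene, rose 2.3-fold from 7.69 ± 0.99 to 17.7 ± 2.53 CPM (adjusted p = 0.00163), and Hvcn1, a proton channel gene, fell from 59.9 ± 1.46 to 32 ± 2.81 CPM (log2 fold change -0.90, SE 0.0982, adjusted p = 0.00163). In Ebf1-ER cells Cybb and Cdh17 were also higher after withdrawal, at 333.1 against 72.75 CPM and 263.2 against 117.2 CPM. Hvcn1 went the other way there, from 21.15 to 30.23 CPM. In Ebf1 cells Myc stood at 1107 ± 224 and 1122 ± 160 CPM (log2 fold change 0.02, SE 0.192, adjusted p = 0.995), and Ebf1, Esr1, Pax5 and Cd19 had adjusted p of 0.985, 0.652, 0.966 and 0.997.

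Of the genes on the lists, 5 changed in Ebf1 cells, and they are named after their values were seen. Rag1, a recombinase gene, rose from 105.7 ± 6.02 to 199.2 ± 8.59 CPM (log2 fold change 0.91, SE 0.0871, adjusted p = 0.000712), beside a rise of 1.08 (SE 0.0869) in Ebf1-ER cells. Kit rose from 42.4 ± 1.15 to 65.3 ± 3.02 CPM (log2 fold change 0.62, SE 0.0927, adjusted p = 0.0132) and Jun, an immediate-early gene, by 0.70 (SE 0.105). The B lineage gene Nedd9 fell by 0.56 (SE 0.1) and Lss fell by 0.46 (SE 0.0869). The calls of Rag1, Kit, Jun, Nedd9 and Lss in Ebf1 cells were not refitted without single samples.

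Gng4 rose by 1.18 (SE 0.177), Nrxn2 fell by 1.58 (SE 0.219) and Zfp948 fell by 0.90 (SE 0.137) in Ebf1 cells. These calls depended on single samples. Gng4 was lost without Ebf1 4OHT replicate 1 or 2 or withdrawn Ebf1 replicate 1 or 3 (adjusted p up to 0.0929), Nrxn2 without Ebf1 4OHT replicate 2 or withdrawn Ebf1 replicate 1 or 2 (up to 0.0669), and Zfp948 without Ebf1 4OHT replicate 1 or 2 or any withdrawn Ebf1 replicate (up to 0.0856). In all, 47 genes changed, 29 higher and 18 lower, with 11 by at least 2-fold and 1214 at an unadjusted p under 0.05. With library totals the split was 14 higher and 18 lower. With replicates 1 and 2 summed, Cybb (0.118), Cdh17 (0.431), Hvcn1 (0.439), Gng4 (0.692), Nrxn2 (0.645) and Zfp948 (0.787) did not pass, though their log2 fold changes were 1.99, 1.22, -0.92, 1.21, -1.61 and -0.90. With that sum and a batch term Cybb (1.52e-05), Cdh17 (2.86e-05), Hvcn1 (0.00105), Gng4 (0.00107), Nrxn2 (0.000151) and Zfp948 (0.0484) passed. The count was 535 with the replicate block, 299 higher and 236 lower, 1001 with replicates 1 and 2 alone, and 7, 6, 18, 7, 17 and 17 without Ebf1 4OHT replicates 1, 2 and 3 and withdrawn Ebf1 replicates 1, 2 and 3. Of the genes called in replicates 1 and 2 that had a value in replicate 3, 84.8% had the same sign there. Camera called 0 of 20 lists, 9 had an unadjusted p under 0.05, and fry called 4. The lowest adjusted p was 0.0836, for cholesterol synthesis (0.0113 with the replicate block, and 0.0142 without Ebf1 4OHT replicate 3) and for cytokine and homing receptors (0.0142 without that sample). Estrogen targets had 0.087 and passed without the same sample (0.0329).

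The difference between the withdrawal effects asks which changes in Ebf1-ER cells went beyond those in Ebf1 cells. The surrogate light chain gene Igll1 fell 22.8-fold further in Ebf1-ER cells (log2 difference -4.51, SE 0.163, edgeR adjusted p = 9e-09), and Vpreb2 and Vpreb3 fell further by 2.59 (SE 0.235) and 2.02 (SE 0.189). Myc fell further by 1.48 (SE 0.273, adjusted p = 0.00275), by 1.32 to 1.67 in the 3 replicate numbers. Kit rose further by 1.75 (SE 0.131), Lyz2 by 4.04 (SE 0.401) and Itgam, an integrin gene of myeloid cells, by 4.16 (SE 0.193). Bmf rose further by 2.84 (SE 0.214), and Bcl6, a repressor of the pre-B stage, by 2.61 (SE 0.335).

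Ribosome biogenesis had 17 of 35 members lower and none higher in the difference (26 and 0 adjusted over the list alone; median -0.59, adjusted p = 2.64e-12; adjusted p = 0.0282 with an estimated correlation). At G1/S, 12 of 27 were lower and none higher (21 and 0 adjusted over the list alone; adjusted p = 6.53e-11), with Ccnd2 at -1.26 (SE 0.203) and Ccnd3 at -0.998 (SE 0.168), a call lost with replicates 1 and 2 summed (adjusted p = 0.0737). Ccnd3 fell from 342.6 to 187 CPM in Ebf1-ER cells and stayed above Ebf1 cells, at 100.5 CPM with 4OHT and 109.6 CPM after withdrawal. At G2/M, 5 of 22 were lower and none higher (12 and 0 adjusted over the list alone; adjusted p = 3.55e-06). Of the B lineage genes, 9 were lower and 4 higher (10 and 5 adjusted over the list alone; adjusted p = 0.00188; adjusted p = 0.189 with an estimated correlation). Myeloid genes were higher for 4 of 6, also when adjusted over the list alone (adjusted p = 8.72e-05). Dendritic and MHC class II genes were higher for 9 and lower for 1 of 12, also when adjusted over the list alone (adjusted p = 1.76e-07), H2-Ab1 by a fitted 9.77 (SE 1.18) that rests on 8 counts with 4OHT and 1 after withdrawal in Ebf1 cells. Stromal genes were higher for 8 of 17 (10 adjusted over the list alone; adjusted p = 8.41e-06), and moved with the lineage genes here too. The T, NK and innate lymphoid list had 6 higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 4.49e-05), with Klrd1 at 3.49 (SE 0.23). Stem and progenitor genes were higher for 4 of 8, also when adjusted over the list alone (adjusted p = 0.000954). Histone genes were lower for 6 of 17, also when adjusted over the list alone (adjusted p = 0.000142; adjusted p = 0.0997 with an estimated correlation). Cytokine and homing receptors were higher for 9 of 21 and lower for 1 (10 and 1 adjusted over the list alone; adjusted p = 8.65e-05; adjusted p = 0.0687 with an estimated correlation).

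Altogether 1924 genes had a withdrawal effect that differed between constructs, 1234 higher and 690 lower in Ebf1-ER cells, and 803 by at least 2-fold. Camera called 15 of 20 lists and 8 with an estimated correlation. The replicate block gave 4190 genes, 2302 higher and 1888 lower, replicates 1 and 2 alone gave 4909, of which 88.8% of those with a value kept their sign in replicate 3, and their sum gave 424, or 2640 with a batch term. Pax5 (adjusted p = 0.589), Cd19 (0.126) and Ebf1 (0.276) did not pass, but did with the replicate block at 0.0468, 0.00435 and 5.67e-05. With replicates 1 and 2 summed and a batch term Cd19 (0.0222) and Ebf1 (0.00218) passed and Pax5 (0.283) did not, and Cd19 also passed without withdrawn Ebf1-ER replicate 3 (0.00682). Myc was not called with replicates 1 and 2 summed (adjusted p = 0.079, or 9.6e-08 with a batch term added) or without replicate number 1 (0.0658) or 2 (0.111).

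With 4OHT present, the comparison asks whether cells with the fusion and cells with EBF1 itself differed before withdrawal. Sox11, a transcription factor gene on chromosome 12, had 51.5 ± 4.95 CPM in Ebf1 cells and no count in Ebf1-ER cells, which puts it at least 1130-fold lower there. D630039A03Rik was at least 354-fold lower. Nrxn2, with 3 counts in Ebf1-ER cells, stood at a ratio of 1190 (95% counting interval 408 to 5790). The histone demethylase gene Kdm5d on chromosome Y had 72.3 ± 8 CPM in Ebf1-ER cells and none in Ebf1 cells, at least 1360-fold higher, and Ccnb1ip1 and Bicd1 were at least 463-fold and 366-fold higher. These bounds use a floor of 3 counts over the 3 samples of a group. The labels do not show separate starting cultures within a construct. P-values between constructs, here and after withdrawal, therefore do not cover differences between starting cultures.

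G1/S genes were higher in Ebf1-ER cells for 15 of 27 and lower for 2 (18 and 2 adjusted over the list alone; adjusted p = 2.91e-07; adjusted p = 0.00288 with an estimated correlation). G2/M genes were lower for 15 of 22 and higher for none (17 and 0 adjusted over the list alone), with the same pair of adjusted p-values. Stem and progenitor genes were higher for 6 of 8, also when adjusted over the list alone (adjusted p = 0.000151), and dendritic and MHC class II genes for 6 of 12, with 1 lower (7 and 1 adjusted over the list alone; adjusted p = 4.11e-05). Camera called 10 of 20 lists, and 4 of them, those just described, were also called with an estimated correlation. Ebf1 had an adjusted p of 0.961 and Cd19 of 0.369. Myc had a log2 difference of -0.39 (SE 0.192, adjusted p = 0.202) and Pax5 of -0.26 (SE 0.152, adjusted p = 0.294), and both passed with the replicate block (2.33e-05 and 0.000983). Esr1 had a log2 difference of 0.29 (SE 0.0922, adjusted p = 0.0428), a call lost without any single sample of the 6, with adjusted p from 0.0596 without Ebf1 4OHT replicate 3 to 0.129 without Ebf1 4OHT replicate 2. It was also lost with no filter (0.0805), only the groups compared (0.0887), and replicates 1 and 2 summed without (0.305) and with a batch term (0.0861).

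In this comparison 2354 genes differed, 1031 higher and 1323 lower in Ebf1-ER cells, and 1053 by at least 2-fold. With library totals the split turned to 1485 higher and 1040 lower. The replicate block gave 4230 genes, 2068 higher and 2162 lower, replicates 1 and 2 alone gave 5040, of which 87.8% of those with a value had the same sign in replicate 3, and their sum gave 1081, or 2902 with a batch term.

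After withdrawal, when only Ebf1 cells had drug-independent EBF1, Myc was lower and myeloid, dendritic and MHC class II genes were higher in Ebf1-ER cells. Myc was 3.65-fold lower in Ebf1-ER cells, at 307.3 ± 76.6 against 1122 ± 160 CPM (log2 difference -1.87, SE 0.198, edgeR adjusted p = 6.42e-06). G2/M genes were lower for 20 of 22 and higher for none (21 and 0 adjusted over the list alone; adjusted p = 3.03e-10). G1/S genes were higher for 3 of 27 and lower for 4, also when adjusted over the list alone (median -0.04). Camera did not call that list (adjusted p = 0.308), though fry did (0.000168). B lineage genes were higher for 8 of 23 and lower for 10, also when adjusted over the list alone (median -0.08). Camera did not call this list either (adjusted p = 0.233), though fry did (0.000332). Dendritic and MHC class II genes were higher for 10 of 12 and lower for none (10 and 1 adjusted over the list alone; adjusted p = 2.9e-07), and myeloid genes for 5 of 6, also when adjusted over the list alone (adjusted p = 0.000301). Stromal genes were higher for 12 of 17 and lower for 1 (13 and 1 adjusted over the list alone; adjusted p = 0.000521; adjusted p = 0.082 with an estimated correlation). Of the T, NK and innate lymphoid genes 5 were higher and 3 lower, also when adjusted over the list alone (median 0.60, mean -0.16), and camera did not call the list (adjusted p = 0.297) while fry did (4.04e-05). Ribosome biogenesis genes were lower for 23 of 35 and higher for none (25 and 0 adjusted over the list alone; adjusted p = 4.18e-07; adjusted p = 0.082 with an estimated correlation).

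Sox11 was at least 1200-fold, Gfra2 at least 769-fold and D630039A03Rik at least 408-fold lower in Ebf1-ER cells. Kdm5d was at least 1670-fold, Nfam1 at least 1220-fold and Bicd1 at least 327-fold higher. Esr1 was 1.7-fold higher (log2 difference 0.77, SE 0.0914, adjusted p = 1.82e-05), and Pax5 had an adjusted p of 0.802. Ebf1 (0.0804) and Cd19 (0.145) did not pass, but did with the replicate block (3.79e-07 and 0.00703). With replicates 1 and 2 summed and a batch term Ebf1 (2.8e-05) passed and Cd19 (0.0893) did not. The call was also gained, for Ebf1, with library totals (0.0276) and without withdrawn Ebf1 replicate 3 (0.0483) or, for Cd19, without withdrawn Ebf1-ER replicate 3 (0.00385). In all 4890 genes differed, 2646 higher and 2244 lower, and 2035 by at least 2-fold. Camera called 11 of 20 lists, and 6 with an estimated correlation. Replicates 1 and 2 alone gave 7348 genes, of which 91.9% of those with a value had the same sign in replicate 3, and their sum gave 2854, or 5484 with a batch term.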

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

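The tests on genes read in 1 construct, and those on myeloid and MHC class II genes for granulocytes or macrophages and for a difference between replicates, were chosen only after the results were seen, and the other tests before. The results below are those whose withdrawal effect differed between Ebf1-ER and Ebf1 cells by the edgeR test of the difference itself, and each value is the log2 effect in Ebf1-ER cells minus that in Ebf1 cells. Of 79 named genes tested, 68 differed, as did 15 lists by camera. Most of these genes were named because they passed after Ebf1-ER withdrawal or in the difference, so their share was largely set in advance. Over all 12913 genes tested, 1924 differed. Groups of 3 were too small for a test of single outlying samples.

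Among the target and B lineage genes the values were 0.48 for Esr1, -4.51 for Igll1, -2.95 for Cplx2, -1.94 for Bst1, -2.59 for Vpreb2 and -2.02 for Vpreb3. Of the pre-B transition, Cd2 had 3.10, Dntt 2.13 and Bcl6 2.61. In the MYC network, Myc had -1.48, Mxd4 1.34, Mxd1 0.95 and Mycn 0.77. Ribosome biogenesis genes had -0.95 (Polr1b), -1.15 (Rrs1), -0.85 (Ppan) and -0.82 (Srm). Cell cycle and histone genes had -1.26 (Ccnd2), -0.998 (Ccnd3), -0.93 (Uhrf1), -0.51 (Aurkb), -0.50 (Ccna2), -0.76 (Hist1h2ac), -0.79 (Hist1h1b) and -0.82 (Hist1h4a). Cdkn2a had -1.48, Cdkn1a -1.20, Sesn1 0.80, Bmf 2.84, Bcl2l11 0.78 and Bax -0.86. Of glycolysis, Hk1 had 1.82, Pfkp -0.56 and Ldha -0.85. Receptor and progenitor genes had 2.01 (Sell), 3.28 (S1pr1), 1.75 (Kit) and 2.93 (Ly6a). T, NK and innate lymphoid genes had 3.49 (Klrd1), 3.32 (Il18r1), 2.49 (Nkg7), 3.16 (Id2) and -2.84 (Tcf7). Myeloid and MHC class II genes had 4.04 (Lyz2), 3.87 (Fcgr3), 4.16 (Itgam), 9.77 (H2-Ab1) and 5.99 (H2-Eb1). Col5a1 had 2.31, Kitl 1.69, Ier3 3.50, Fos 3.11, Oasl2 3.79, Irf7 1.996, Pgr 5.08 and Igfbp4 0.83. Outside the lists, AA467197 had 7.51, Crisp1 5.14, Scn3a 6.39, Mir147 8.004, Ms4a4c 5.47, Clgn -6.08, H19 -3.99, Rragd -3.86, Cd248 -3.77, Gfra1 -3.37, Gng4 -6.41 and Gfra2 -7.12. Gfra2 had 0 counts in withdrawn Ebf1-ER cells, so its fitted value is no bound. Gng4 had 2 there and H2-Ab1 had 1 in withdrawn Ebf1 cells. Their fitted values, like all other differences, come without a counting interval. H2-Eb1, Ms4a4c and Mir147 also rested on few counts, at 0.0968, 0.0847 and 0.0642 CPM in withdrawn Ebf1 cells. Pgr rose in Ebf1-ER cells from 0.0699 to 1.91 CPM and stayed below the 54.57 CPM of withdrawn Ebf1 cells. Bst1 and Ccnd3 fell there to 3.41 and 187 CPM and stayed above the 0.934 and 109.6 CPM of withdrawn Ebf1 cells. The differences of Bst1, Dntt, Uhrf1, Hist1h2ac, Sesn1, Bcl2l11, Pfkp, Nkg7, Fcgr3, Scn3a, Mir147, H19, Rragd, Cd248 and Gfra1 were not refitted under any alternative. The losses below concern the other genes. Calls lost without a single sample were those of Esr1 (replicates 1 and 2 of each group, adjusted p up to 0.0827), Aurkb (Ebf1-ER 4OHT 1 and 2, Ebf1 4OHT 1, 2 and 3, withdrawn Ebf1 1 and 2, up to 0.0712), Cdkn2a (Ebf1-ER 4OHT 2, withdrawn Ebf1-ER 1, Ebf1 4OHT 1 and 2, withdrawn Ebf1 2, up to 0.0726) and Mxd1 (Ebf1-ER 4OHT 1 and 2, Ebf1 4OHT 3, withdrawn Ebf1 2 and 3, up to 0.0711). Cd2 was lost without Ebf1-ER 4OHT 1 or 2, any withdrawn Ebf1-ER sample, Ebf1 4OHT 1 or withdrawn Ebf1 1 or 2 (up to 0.916), and Tcf7 without any of the 12 samples but Ebf1-ER 4OHT 2 (up to 0.0998). Hist1h4a was lost without replicates 1 or 2 of either Ebf1-ER group or of Ebf1 4OHT, or withdrawn Ebf1 1 or 3 (up to 0.0822). Ier3 was lost without Ebf1-ER 4OHT 2, Ebf1 4OHT 2 or 3 or withdrawn Ebf1 1 or 2 (up to 0.126), and Kitl without Ebf1-ER 4OHT 2, withdrawn Ebf1-ER 1 or 2, Ebf1 4OHT 1 or any withdrawn Ebf1 sample (up to 0.09). Ldha was lost without Ebf1-ER 4OHT 2 or withdrawn Ebf1 1 or 2 (up to 0.059), H2-Eb1 without Ebf1 4OHT 2 (0.0615) or 3 (0.333), and Ms4a4c without Ebf1 4OHT 3 (0.0712).

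With replicates 1 and 2 summed, 26 of the refitted calls were lost, with adjusted p from 0.0502 (Rrs1) to 0.356 (Esr1). They were Myc (0.079), Cd2 (0.0913), Mxd4 (0.113), Mxd1 (0.143), Mycn (0.108), Ppan (0.0639), Srm (0.132), Ccnd3 (0.0737), Aurkb (0.263), Ccna2 (0.192), Hist1h4a (0.292) and Hist1h1b (0.0874). Further losses were Cdkn2a (0.152), Cdkn1a (0.151), Bax (0.0857), Ldha (0.173), Sell (0.0755), Tcf7 (0.178), H2-Eb1 (0.0657), Kitl (0.176), Ier3 (0.155), Oasl2 (0.0651), Irf7 (0.0857) and Igfbp4 (0.0884), besides Rrs1 and Esr1. With a batch term added to the sum, Esr1 (0.0892), Cdkn2a (0.0602) and Kitl (0.0537) were lost. Library totals lost Cd2 (0.0535), Aurkb (0.0706) and Ldha (0.052), voom lost Cd2 (0.116) and Tcf7 (0.0782), and no filter lost Esr1 (0.108).

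The list medians of the difference were -0.42 for the B lineage, -0.59 for ribosome biogenesis, -0.48 for G1/S, -0.38 for G2/M, -0.40 for glycolysis and -0.54 for histones. They were 0.44 for cytokine and homing receptors, 1.24 for T, NK and innate lymphoid genes, 3.94 for myeloid genes, 2.87 for dendritic and MHC class II genes, 0.65 for stem and progenitor genes, 1.14 for stroma, 1.18 for immediate-early genes, 0.93 for interferon-induced genes and 0.45 for estrogen targets. With an estimated correlation 7 of these calls were lost, those of the B lineage (adjusted p = 0.189), glycolysis (0.226), histones (0.0997), cytokine and homing receptors, immediate-early genes and estrogen targets (0.0687 each) and interferon-induced genes (0.0578). The call of estrogen targets was also lost without withdrawn Ebf1-ER replicate 3 (adjusted p = 0.0638) or Ebf1 4OHT replicate 3 (0.0553), with the replicate block (0.0709), library totals (0.0657), a batch term (0.0663) and replicates 1 and 2 summed (0.0515). The call of glycolysis was also lost without Ebf1 4OHT replicate 3 (0.0523) and with fry (0.0755).

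In 34 genes, counts were read in 1 construct and at most 3 counts over the 6 samples of the other, 11 in Ebf1-ER cells and 23 in Ebf1 cells. Weaker EBF1 activity of the fusion would have most of the 11 rise further after Ebf1-ER withdrawal. Only 2 of them (Nova1 and Nfam1) rose, while 3 fell and 6 were not called. That argues against this cause for the 3 that fell (Kis2, En2 and Ccnb1ip1). The 2 that rose went with it, Nfam1 from 12 to 61.8 CPM. The 6 not called cannot decide, since a gene already fully raised need not rise further. Chromosome stretches lost or silenced in 1 culture cannot be told apart from other causes, since 2 genes (Nhsl1 and Arfgef3 on chromosome 10) lay next to another of the same direction against 0.1 in random draws (permutation p = 0.048). The Y-linked gene Kdm5d had 72.3 and 82.9 CPM in Ebf1-ER cells and 0 in Ebf1 cells, and Uty had 43.4 and 49 against 7.82 and 10.2 CPM, while Ddx3y had 70.3 and 79.4 against 56.4 and 56.2 and Eif2s3y 68.8 and 64.3 against 62.6 and 57.6 CPM. A difference in the origin of the starting cells was not tested and stays open, as does any cause for the 23 genes of Ebf1 cells.

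Stromal genes were higher after Ebf1-ER withdrawal, with a list median of 1.39. RNA from OP9 feeder cells stays open, since a second list of 28 measured stromal genes had a median of 1.51 (95% bootstrap interval 1.24 to 1.72), of which 20 rose and 0 fell. The value of Lox on that list had been seen before. Lum and Dcn of the first list had 0 counts over all samples, but their level in OP9 cells was not measured here. The sort for CD19 should leave out OP9 cells, but its purity was not measured here. Col1a1 was read at 7.85 and 28 CPM in Ebf1-ER cells and at 8.53 and 12.3 CPM in Ebf1 cells, with 4OHT and after withdrawal. A difference between replicates 1 and 2 and replicate 3 was argued against, with medians of 1.45, 1.41 and 1.25 in the 3 replicate numbers. A change within the sorted cells after loss of EBF1 activity was not tested apart from this and stays open.

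Myeloid and MHC class II genes were higher after Ebf1-ER withdrawal, with medians of 3.88 for the myeloid and 2.91 for the dendritic list. Granulocytes or macrophages were argued against, since the 15 myeloid genes under 1 CPM in Ebf1-ER cells with 4OHT had a median of 0.0147 CPM after withdrawal against 217 CPM for Lyz2 (0 for S100a8, S100a9, Mpo, Elane and Adgre1, 0.0595 for Cd14, 0.264 for Csf1r), and 1 of them, Fcgr3 at 15.6 CPM, reached 5% of Lyz2. Dendritic cells cannot be told apart from a change within the cells, since a second dendritic list rose by 120 CPM (Cst3 from 86.5 to 149 CPM, Ctss from 51.8 to 106), 7.07% of the rise of 1700 CPM in Cd74, but the share they would need rests on an assumed profile, and Siglech, a gene of plasmacytoid dendritic cells, rose from 3 to 332 counts (ratio 99.5, 95% counting interval 33.8 to 485). The sort for CD19 should leave out such cells, but its purity was not measured here. A difference between replicates was argued against, with medians of 3.58, 3.09 and 3.13 in the 3 replicate numbers over the 18 measured genes of both lists, and a rise within the cells when EBF1 activity is lost stays open.

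Other splits of the samples were counted for each comparison. The 10 splits of 6 samples are too few for a share under 0.05. For Ebf1-ER withdrawal the real split gave 4337 genes and 16 lists and the highest other 0 and 11, and for Ebf1 withdrawal 47 genes and 0 lists against 0 and 1 (9 lists had an unadjusted p under 0.05, and fry called 4), with all 10 splits at 0 lists or more. Between constructs, the real splits gave 2354 and 4890 genes and the highest others 0. For the difference, 5 of 100 drawn splits of 200 possible gave as many genes as the real 1924, and 5 as many lists as the real 15, with 2365 genes and 16 lists as the highest others, both counts with the real split included. A share of 0.05 is not under the limit set for excluding chance. Among splits that part all replicate pairs the highest other was 2160 genes. Each of the 8 other splits with any gene called kept the real grouping of the Ebf1-ER samples and regrouped Ebf1 samples, so these splits still held the Ebf1-ER withdrawal effect and are no measure of chance alone.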

How the results depend on the processing

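The batch term, the sums of replicates 1 and 2 and the removal of Rn45s and Mir6236 were chosen only after the data were seen. No called named gene or list changed direction under the alternatives run, but with library totals the split of the counts turned to 1485 higher and 1040 lower with 4OHT (from 1031 and 1323), 14 and 18 after Ebf1 withdrawal (from 29 and 18) and 2125 and 2133 after Ebf1-ER withdrawal (from 2519 and 1818). With the replicate number as a block, 535 genes changed after Ebf1 withdrawal, 4190 in the difference and 4230 between constructs with 4OHT, and 1 list was called after Ebf1 withdrawal. Among the named genes and the lists refitted with it, the block changed no call apart from those given beside their results. Lists compared between constructs were not refitted with the block. DESeq2 gave 219 genes for Ebf1 withdrawal, and only the groups compared gave 9. An estimated correlation left 8 lists in the difference, and fry called 4 lists after Ebf1 withdrawal. With a batch term for replicates 1 and 2 against 3, the counts were 6632 for Ebf1-ER withdrawal, 696 for Ebf1 withdrawal (2 lists), 4457 for the difference and 4502 with 4OHT. With replicates 1 and 2 summed they were 1910, 0, 424 and 1081, and 2854 after withdrawal. For that count of 0, edgeR on all samples gave 1214 genes at an unadjusted p under 0.05 and 47 adjusted, and DESeq2 219. With the sum and a batch term they were 5017, 111, 2640, 2902 and 5484, and the calls of named genes lost were those of Esr1, Cdkn2a and Kitl in the difference and Esr1 with 4OHT. Leaving out single samples or replicate numbers gave 1692 to 7008 genes for Ebf1-ER withdrawal, 0 to 1001 for Ebf1 withdrawal, 350 to 4909 for the difference, 936 to 5040 with 4OHT and 2659 to 7348 after withdrawal. Each lowest count was without replicate 2 and each highest without replicate 3, and counts without replicate 1 were 1834, 1, 396, 1010 and 2723. Fewer samples and a different spread enter these fits together, so the cause was not tested. Leave-one-out list counts for Ebf1 withdrawal ran from 0 to 3 (without Ebf1 4OHT replicate 3). Over named genes, called or not, 1500 leave-one-out results stayed on their side of the threshold, 180 calls were lost and 15 gained, and over lists 468 stayed, 9 calls were lost and 3 gained. Library totals moved the median log2 fold change of all genes by at most 0.096. Summing repeated symbols could not be run, lists were not run without a filter, and only the groups compared gives no separate fit of the difference. Depth limits genes at few counts. A bound or counting interval is given for some folds between 2 groups. The differences between the withdrawal effects are all fitted values with neither. Those of Gng4, Gfra2, H2-Ab1, H2-Eb1, Ms4a4c and Mir147 rest on few counts in at least 1 group.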

Other observations

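The lists in this part were chosen only after the results were seen, and the tests on them as well. After Ebf1-ER withdrawal, genes of amino acid synthesis and the ATF4 response fell together, 20 of 22 measured and none rising, also when adjusted over the list alone (median log2 fold change -0.84, camera adjusted p = 8.15e-14; adjusted p = 0.00056 with an estimated correlation). Asns, the asparagine synthetase gene, fell by 2.53 (SE 0.146), Bcat1 by 1.54 (SE 0.102) and Shmt2 by 0.86 (SE 0.0823). In the difference between the withdrawal effects, 14 were lower and none higher (19 and 0 adjusted over the list alone; adjusted p = 7.64e-14).

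Integrin genes rose for 7 of 16 measured and fell for 1, also when adjusted over the list alone (adjusted p = 0.00288; adjusted p = 0.022 with an estimated correlation), with Itgb7 rising by 4.04 (SE 0.228) and Itgal by 1.76 (SE 0.138). MHC class I genes rose for 6 of 12 and fell for 1 (8 and 1 adjusted over the list alone; adjusted p = 0.00288; adjusted p = 0.0271 with an estimated correlation), B2m by 0.69 (SE 0.0903) and H2-T23 by 1.46 (SE 0.142). Of 7 Notch targets, 1 rose and 2 fell (2 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.363). Hes1 fell by 1.81 (SE 0.174) and Notch1 rose by 1.18 (SE 0.126). After Ebf1 withdrawal none of these 4 lists was called by camera, with adjusted p from 0.237 to 0.57.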
